A study of Mus musculus with 107 samples.

How the data were processed

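The series comprises 107 samples. RNA was measured by stranded mRNA sequencing in the parental B6NJ line and 8 deletion clones, and chromatin contacts by ChIA-PET in E14 cells and B6NJ lines. Samples were grouped by the clone, line and target that their labels give. The labels do not say whether replicates came from separate cultures, so p-values measure the spread between these samples, which may be technical.

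The deposited gene counts are whole numbers, not normalized. Per the submitters' processing notes, reads of 25 RNA libraries were trimmed with Trim Galore 0.4.0, aligned with HISAT2 2.1.0 and counted with HTSeq 0.6.1 on mm10. For 1 chr3 library no tools are named. Whether counting used the strand is not given in the sources used here, so counts of overlapping antisense genes can be mixed. Peak lists of PRC2, H3K27me3, CTCF and RNA polymerase II were deposited as pooled calls, with a fold enrichment (ratio to background) and a −log10 p per peak. MACS2 2.1.1.20160309, BWA 0.7.12 and cutadapt 1.14 are named in the submitters' processing notes. The pooled PRC2 interaction list holds counts of paired-end tags and p-values, per the file headers, which name ChiaSig. The caller of the deposited Ezh2 interaction lists is not given in the sources used here. Pooling and the authors' thresholds leave no replicate error for the E14 maps, and reads with several positions, 17.8% to 21% per library, were left uncounted, which affects gene families and pseudogenes.

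Rows that name no gene stayed out of library sizes. Reads outside genes made up 5.08% to 8.77% per library and ambiguous reads 1.46% to 1.62%. Of 51435 gene IDs, 99.6% matched a symbol, and 72.5% had a position in the RefSeq table (GRCm38.p6), which gives no strand, so both ends of a gene were used as possible start sites. After edgeR's filterByExpr, 19993 genes were tested with TMM factors and the quasi-likelihood test (edgeR 4.0.16, limma 3.58.1, R 4.3.3) in 1 model of all 26 libraries, with Benjamini-Hochberg adjustment at 0.05. Each deletion was compared as the mean of its 2 clones minus the parental line. Further comparisons took each clone minus the parental line, clone against clone, and the deletion minus the 6 clones of other deletions. The common biological coefficient of variation was 7.39%. Replicate pairs differed by 3.78 to 13.4 times the sampling noise, so no library was counted as a duplicate. At depths of 39.7 to 128 M counts small changes pass the test, so sizes are given beside counts.

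Gene lists were tested with camera (preset correlation 0.01) on log2 CPM with a prior count of 2, adjusted over 24 lists per deletion. Genes named are those called within 1 Mb, within 100 kb or linked to the interval, the 10 largest rises and falls called in both clones with a mean of at least 5 CPM, and up to 4 members of each called list. Symbols of the forms Gm plus digits, Rik, Rp plus digits and -ps were left out of the largest changes. The 10 PRC2 interactions with the most tags were taken among those with anchors at least 20 kb apart at different genes. Lists, names, this limit and main tests were chosen before the data were examined. Peak overlap needed 1 bp and was set against 100 random placements. Ezh2 interactions were counted per 10000 of a library and compared by exact permutation of 4 against 6 libraries, although the 2 libraries of a line share its deletion. Window shares counted every run of consecutive tested genes on a chromosome.

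The model was tested on simulated counts for chr9 against parental with 18674 genes: 98.5% of 67 genes changed by 1.5-fold and 100% of those changed by 2-fold or 4-fold were recovered, with 5 false calls (2.45%). With no change simulated, 0 genes were called for each deletion. Changes were planted only in genes with many counts, and all genes had the same dispersion. No variation between clones or batches was simulated, so these figures do not cover it or genes with few counts. Alternatives were other size factors, filters, DESeq2 1.42.0, the replicate block, the compared libraries only, each library left out, other thresholds, controls and windows, counts thinned to the smallest library, and counts without the X and Y chromosomes. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used. E14 RNA, ATAC and the separate input libraries were not used here.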

Results

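Polycomb repressive complex 2 (PRC2), whose subunits include Eed, Ezh2 and Suz12, places the H3K27me3 mark on histone H3 and keeps developmental genes low in embryonic stem (ES) cells. The series mapped PRC2-bound chromatin contacts in E14 mouse ES cells by ChIA-PET, which joins and sequences DNA ends held together by a bound protein, and then removed PRC2-bound distal elements in B6NJ mouse ES cells. Elements on chromosomes 9, 7, 3 and 2 were deleted, with 2 clones for each deletion, and the undeleted parental B6NJ line served as the control. RNA was counted in 26 libraries, 3 for each line except clone chr9-F1 with 2. The SEs and p-values of RNA changes come from the spread between libraries of a line. They do not cover differences between clones, or between the clones and a single parental line, that are unrelated to a deletion. Ezh2 ChIA-PET was made in 10 libraries, 2 for each of the parental line, chr9-F1, chr9-G9, chr7-D4 and chr7-F4. The total count per RNA library was 90.3 to 128 M in the 8 parental and chr9 libraries and 39.7 to 60.2 M in the 18 libraries of the other deletions. For the chr7, chr3 and chr2 clones this difference in depth coincides with the comparison against the parental line, so the deletion and any library batch cannot be told apart there. It also coincides with the comparison of the chr9 clones with the 6 clones of other deletions, where the same holds.

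In E14 cells PRC2 peaks lay at nearly all H3K27me3 domains and were long there. Of 4347 H3K27me3 peaks, 90.7% held a PRC2 peak, and the 3847 PRC2 peaks with H3K27me3 had a median length of 2956 bp against 276 bp for the 19634 without it. H3K27me3 overlapped 16.4% of the 23481 PRC2 peaks, against a mean of 0.628% ± 0.0474 (SD over 100 random placements). RNA polymerase II ChIA-PET peaks overlapped 55.0% of PRC2 peaks against 4.81% at random, RNA polymerase II ChIP peaks 13.8% against 1.36%, and CTCF peaks 7.16% against 2.08%. These are the authors' pooled peak lists with no replicates, so the spread covers random placement only. With at least 50% of the PRC2 peak covered, the H3K27me3 share was 9.58% and the CTCF share 1.58%.

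Among PRC2 interactions whose anchors lay at least 20 kb apart at different genes, the most paired-end tags (PETs), 1849, linked Hoxb13 to an anchor holding Hoxb2 to Hoxb9 on chromosome 11, and 1538 linked Six3 to Six2 on chromosome 17. Nkx2-1 was linked to Pax9 (907 PETs), Tbx2 to Tbx4 (894), Irx1 to Irx2 over 651 kb (751), Irx3 to Irx5 over 543 kb (703), Foxq1 to Foxf2 (627) and Nkx2-2 to Pax1 (604). Raet1e and H60b, which encode ligands of an immune receptor, shared 1418 PETs, and the anchor at Fev and Cryba2 was linked to Ihh by 668. Of 309853 interactions on the main chromosomes, 18155 (5.86%) had both anchors in a PRC2 peak, 27.2% had 1 and 66.9% had none. The share with both anchors in a peak was 2.79% at 3 PETs and 57.3% at 50 PETs or more. Protein-coding genes with a PRC2 peak within 2 kb of a gene end had a median of 3.31 CPM in parental B6NJ cells, against 4.96 CPM for the others, while fewer of them lay under 1 CPM (37.0% against 44.0%). The mean log2 difference was -0.27 (6521 against 14774 genes, two-sided permutation p = 1e-05, the smallest possible with 100000 resamples). Genes are not independent replicates, and for gene ends in any interaction anchor the difference was -0.0024 (permutation p = 1). It was -0.52 with a narrower distance to the peak and also for gene ends in interactions with both anchors in PRC2 peaks, the latter chosen after seeing the data (permutation p = 1e-05 for each).

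The targeted interval on chromosome 9 (mm10, 37451506 to 37461721, 10216 bp) was intergenic, 18.1 kb from Robo3 and 25.8 kb from Msantd2. It overlapped 1 PRC2 peak (11.9-fold over background in the authors' list) and 1 H3K27me3 peak, which ran past its end to 37462848 and 37462551. It overlapped no CTCF or RNA polymerase II peak. Its 28 E14 interactions carried 535 PETs, with 135 to Robo3, which encodes an axon guidance receptor, 66 to the endothelial adhesion gene Esam, 22 to the homeobox gene Pknox2 and 13 to Nrgn. The interval on chromosome 7 (143440438 to 143450716, 10279 bp) lay 7.62 kb from Cdkn1c, an imprinted gene for the cell cycle inhibitor p57, and 13.4 kb from Kcnq1. It overlapped 3 PRC2 peaks, the strongest at 13.9-fold, and 2 H3K27me3 peaks. Its borders cut the PRC2 peak at 143440246 to 143440954 and the H3K27me3 peak at 143450043 to 143450925. Its 16 interactions carried 983 PETs, of which 901 joined overlapping anchors at Cdkn1c, 25 reached Phlda2, 9 Ascl2 and 5 Kcnq1. Intervals for chromosomes 3 and 2 are not given in the sources used here, so no nearby genes were examined for them.

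Ezh2 interactions at the targeted intervals served as a check of the deletions, since removed DNA gives no reads and its links are lost with it. At the chromosome 9 interval, the 4 chr9 libraries had 0.704 ± 1.41 (SD, n = 4) interactions per 10000 and the 6 others 9.27 ± 2.39 (SD, n = 6; exact permutation test, two-sided p = 0.00952, the smallest possible). The links to Robo3 and to Esam were found in 6 of 6 libraries without the deletion and in 1 of 4 with it, the library labelled chr9-F1 replicate 1, and those to Pknox2 in 2 of 6 and 0 of 4. Of 2 anchors at Nrgn, the one with 13 PETs in E14 cells was linked in 2 of 6 and 0 of 4 and the one with 9, which also held Vsig2, in 4 of 6 and 0 of 4. The title of chr9-F1 replicate 1 names the clone while its cell type label names B6NJ primary cells. Without that library the chr9 value was 0 and the difference -9.27 per 10000. At the chromosome 7 interval the values were 2.75 ± 2.21 (SD, n = 4) and 8.43 ± 3.49 (SD, n = 6; exact permutation p = 0.0286). With at least 50% of an anchor inside the interval, a setting chosen after seeing the data, the chr7 libraries had 0 and the others 6.92 ± 3.5 (exact permutation p = 0.00952). The link to Phlda2 was found in 5 of 6 libraries without the deletion and 0 of 4 with it. That to Kcnq1 was found in 5 of 6 and 3 of 4, and that to Ascl2 in 0 of 6 and 0 of 4. A link needed only an anchor touching the interval. Those left at Kcnq1 had under 50% of the anchor inside it, so they do not show a kept contact of the removed DNA. The chromosome 7 difference missed the threshold (exact permutation p = 0.0714) without chr7-D4 replicate 2, chr7-F4 replicate 1 or chr7-F4 replicate 2, and when the number was not scaled (p = 0.114 in the exact test). These tests exchanged libraries, 2 of which share each line; with the mean of each line, chosen after seeing the data, the exact permutation p was 0.2 at both intervals, the smallest possible for 2 lines against 3.

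**Figure D1:**
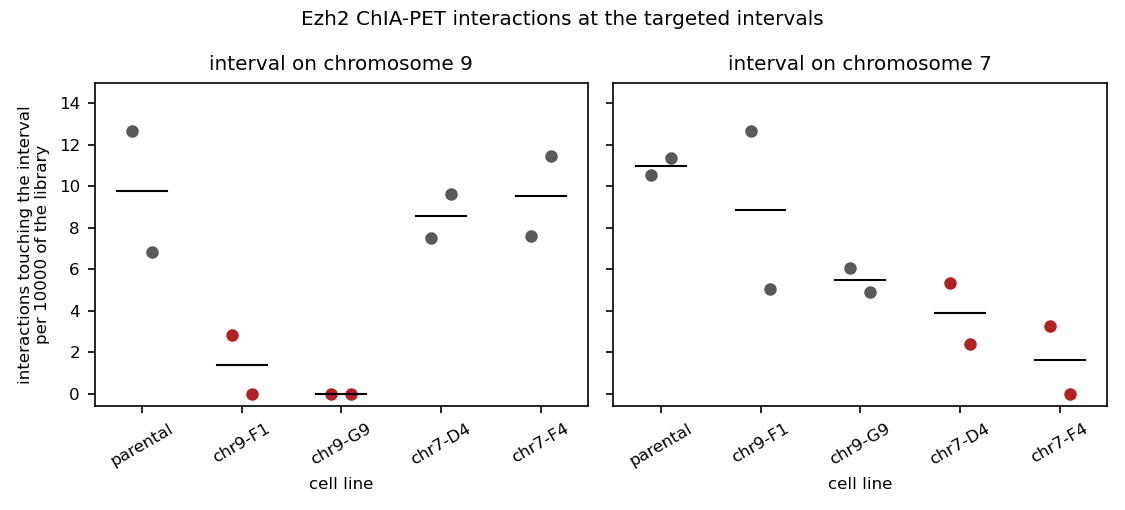
Ezh2 ChIA-PET interactions with an anchor touching the targeted interval on chromosome 9 (left) or 7 (right), per 10000 interactions of each library, for 5 lines on the x axis. Points are the 2 libraries of a line, bars their mean, and red marks the clones with that deletion, which averaged 0.704 on chromosome 9 and 2.75 on chromosome 7.

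Interactions around the intervals did not differ detectably in number. Within 1 Mb and outside the interval, the chr9 libraries had 13.4 ± 3.85 (SD, n = 4) per 10000 and the others 13.1 ± 7.36 (SD, n = 6; exact permutation p = 0.895). Around the chromosome 7 interval the values were 29.4 ± 3.75 (SD, n = 4) and 28.1 ± 7.4 (SD, n = 6; exact permutation p = 0.752). Unscaled, the chr7 libraries had 6.08 more interactions (exact permutation p = 0.0381), and the sign of both small differences changed when single libraries were left out.

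Near the chromosome 9 deletion, Robo3 was the nearest gene and rose in both clones. Robo3 had 0.46 CPM ± 0.0713 (SD, n = 3) in the parental line, 1.57 ± 0.0137 (SD, n = 2) in chr9-F1 and 1.41 ± 0.0943 (SD, n = 3) in chr9-G9, a log2 change of 1.69 ± 0.304 (SE, adjusted p = 4.2e-05). Hepacam (1.30), Slc37a2 (1.03), Fez1 (0.77), Nrgn (0.73), Pknox2 (0.52), Ccdc15 (0.35), Ei24 (0.32) and Siae (0.20) also rose, and Tbrg1 fell by 0.11. Hepacam and Nrgn were low in the parental line, at 0.222 and 1.17 CPM. Of 21 tested genes within 1 Mb, 9 rose and 1 fell, and adjusted over the list alone 9 rose and 3 fell. Genes called higher made up 42.9% of this window and 17.1% of all tested genes. Against the 6 clones of other deletions 9 genes were higher and 9 lower: Robo4 was higher by 3.15, with 0.271 to 1.52 CPM in those clones and 5.32 in the parental line, Robo3 by 2.84, Slc37a2 by 1.13, Fez1 by 1.05 and Pknox2 by 0.79, while Ccdc15 was lower, at -0.29. Ei24 (0.0353) and Siae (0.0297) were not called against those clones, and 6 of the 9 rises over the parental line were. Esam (0.28), Vsig2 (0.33), Spa17 (0.13) and Msantd2 (0.01) did not pass the test against the parental line. Robo4, which lies beside Robo3, was at 1.02 in chr9-F1 and -0.33 in chr9-G9, and the clones differed (adjusted p = 1.96e-05). Elsewhere in the genome, 5.98% of windows of 21 consecutive tested genes held at least 9 genes called higher.

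Across the genome the largest rises in the chr9 clones were in the X-linked Xlr genes. Xlr5b rose from 0.131 CPM ± 0.0361 (SD, n = 3) to 6.29 ± 0.014 (SD, n = 2) and 16.7 ± 1.67 (SD, n = 3), a log2 change of 6.29, and Xlr5a, Xlr5c, Xlr3c, Xlr4b, Xlr4a and Xlr3a rose by 3.82 to 6.21. Pramel6 rose by 4.99, Pramel7 by 4.45 and Nlrp4c by 3.63. These families have near-identical copies, so the share of reads given to each member is uncertain. The largest falls were in Grb10 (-1.67), an imprinted growth factor receptor adaptor, Phlda2 (-1.46), Lars2 (-1.35; 750 CPM ± 493 in the parental line, SD, n = 3, and -0.77 without parental replicate 2), Zmat4 (-1.28), Cdc42ep2 (-1.23), Grin1 (-1.17), Bmp4 (-1.12), Cpt1b (-1.11), Crmp1 (-1.10) and Krt17 (-1.09). Against the other clones Zmat4, Cdc42ep2 and Bmp4 had the opposite sign. Grb10 had 65.6 and 95.4 CPM in the chr9 clones, within the 26.6 to 188 CPM of the 6 other clones. Of 19993 genes tested, 7544 were called (3423 higher, 4121 lower) at an adjusted p of 0.05 in edgeR's quasi-likelihood test, and 3165 were called in the same direction in both clones (1666 higher, 1499 lower). Independent lists would share 514 and 591. Here and for the other deletions both clones were compared with the same 3 parental libraries, so their lists are not independent. Against a 1.5-fold change 784 were higher and 111 lower, and of the shared genes 764 were higher and 54 lower by at least 2-fold in the mean of the clones. The clones differed from each other in 6294 genes, clone chr9-F1 alone called 4851 genes, and 14370 differed from the 6 other clones. Without chr9-F1 replicate 1 the shared count was 2036 and the clone difference 4040, and without replicate 2 they were 2056 and 3899, since 1 library then stood for that clone.

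Of 24 lists fixed before the data were examined, 12 were called in the chr9 clones. Of 23 genes of the 2-cell-like state, 22 rose and 0 fell (camera adjusted p = 8.71e-11), among them Zscan4a (1.61), Zscan4d (1.68), Tcstv1 (2.21) and Zscan4c (1.46). Imprinted genes outside the Cdkn1c region rose in 23 of 29 cases with 3 falls (8.71e-11), with Peg3 at 1.07, Peg10 at 1.24 and Plagl1 at 1.49. Germline genes rose in 16 of 22 cases with 2 falls (adjusted p = 1.26e-10), with Dazl at 2.76, Sohlh2 at 1.12, Taf7l at 1.86 and Hormad1 at 1.01. Primitive endoderm genes rose in 14 of 22 cases with 0 falls (1.73e-06), with Cited1 at 2.57, Rhox5 at 1.15, Col4a1 at 0.91 and a 2.29-fold rise of Col4a2. Hox genes rose in 16 of 28 cases with 0 falls (0.000446), with Hoxa9 at 2.72, Hoxd9 at 2.06, Hoxb4 at 1.92 and Hoxc13 at 0.50, most of them from levels under 1 CPM. Of the 16, 4 were called in both clones, and the list medians were 0.505 in chr9-F1 and 1.15 in chr9-G9, beside 0.272 and 1.72 for the markers of feeder fibroblasts. The list of neighbours of the interval rose in 9 of 16 cases with 1 fall (0.000504) and a median of 0.336. In the chr2 clones the same list had a median of 0.387, with 10 genes higher and 2 lower. It was not called there (camera adjusted p = 0.131), but the rise was not particular to the chr9 clones. In the chr9 clones, genes with a PRC2 peak within 2 kb had a median of 0.07. Of 6085, 1447 rose and 1018 fell (0.0168), with Scml2 at 2.30. These 7 lists were also called with an estimated correlation. Adjusted over the list alone, 17 Hox genes rose and 1 fell, and the other counts were the same but for the PRC2 list (1458 and 1029).

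Hypoxia and glycolysis genes fell in the chr9 clones, 19 of 22 with 0 rises (camera adjusted p = 8.71e-11; adjusted p = 0.113 with an estimated correlation). Pdk1 fell by 0.89, Egln3 by 1.07, Egln1 by 0.73 and Bnip3 by 0.67. ER stress and amino acid response genes fell in 11 of 20 cases with 1 rise (0.000204; adjusted p = 0.0967 with an estimated correlation), with Trib3 at -0.72, Vldlr at -0.71, Chac1 at -0.92 and Psat1 at -0.29. Naive pluripotency genes rose in 10 of 23 cases with 4 falls (0.00649; adjusted p = 0.273 with an estimated correlation), with Prdm14 at 0.79, Nanog at 0.51, Fbxo15 at 0.51 and Esrrb at -0.33. Genes of the p53 response rose in 12 of 20 cases with 1 fall (0.000147; adjusted p = 0.12 with an estimated correlation), with Phlda3 at 0.53, Plk2 at 0.48 and Eda2r at 0.46, the last lower than in the other clones (-0.74). Markers of feeder fibroblasts, on which the cells grew, rose in 21 of 25 cases with 1 fall (6.05e-06; adjusted p = 0.186 with an estimated correlation). In chr9-G9 Col1a1 reached 85.3 CPM ± 41.6 (SD, n = 3) against 18.2 ± 5.19 (SD, n = 3) in the parental line. Col5a1 rose by 1.27, Timp3 by 1.03 and Col1a2 by 1.34. Adjusted over the list alone, 21 feeder markers rose and 2 fell, 13 p53 genes rose and 2 fell, and 1 ER stress gene rose and 12 fell. The X-linked median was 0.25 in chr9-F1 and 0.39 in chr9-G9 over 368 genes, beside Y-linked RNA at 14.9% and 19.1% of the parental level. No list was tested again without its X-linked genes, so their share in the rise of a list is not known. This difference in sex-linked RNA coincides with the comparison of the chr9 clones with the parental line. Changes of autosomal genes there cannot be told apart from it either. The remaining 12 lists, which were formative pluripotency, trophoblast, mesoderm, neuroectoderm, Polycomb subunits, imprinted genes near Cdkn1c, cell cycle inhibitors, ERK targets, Wnt targets, cholesterol synthesis, interferon response and gene ends in interaction anchors, were not called (adjusted p 0.0821 to 0.98). Against the 6 clones of other deletions, list tests chosen after seeing the data no longer called germline genes (adjusted p = 0.0963), p53 genes (0.645), neighbours of the interval (0.212) or genes with a PRC2 peak (0.0626). They newly called formative genes (median 0.822, adjusted p = 0.00434), Wnt targets (0.00434) and mesoderm genes (0.0397), all higher in the chr9 clones. The 6 other clones all had the lower range of depth, so depth or batch cannot be told apart from the deletion there.

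Cdkn1c, Slc22a18, Kcnq1, Phlda2 and Cars rose in the chr7 clones, but the fixed list of imprinted genes near Cdkn1c was not called (9 higher and 6 lower of 20, adjusted p = 0.0906). The chr3 clones, which lack this deletion, had the same counts for the list, 9 higher and 6 lower of 20 (camera adjusted p = 0.203). These counts were thus not particular to the chr7 clones. Against the 6 clones of other deletions, a list test chosen after seeing the data, the list was called higher in the chr7 clones (median 0.0999, adjusted p = 0.0203). Cdkn1c had 5.36 CPM ± 0.462 (SD, n = 3) in the parental line, 10.9 ± 1.3 (SD, n = 3) in chr7-D4 and 13.1 ± 1.41 (SD, n = 3) in chr7-F4, a log2 change of 1.16 ± 0.11 (SE, adjusted p = 7.21e-11). Slc22a18 rose by 1.00, Phlda2 by 0.54, Cars by 0.25, and Kcnq1 2.28-fold. Against the 6 clones of other deletions these genes were higher too: Cdkn1c by 1.26, Slc22a18 by 1.52, Kcnq1 by 2.67, Phlda2 by 1.25 and Cars by 0.29. These controls include the chr9 clones, in which Phlda2 was among the largest falls, so part of its 1.25 comes from them. Cdkn1c had 2.77 CPM in chr9-F1 and 4.29 to 7.94 CPM in the other control clones. The noncoding RNA Kcnq1ot1 rose by 1.82 over the parental line but was at -0.20 against the other clones. Farther away H19 rose by 5.26, Igf2 by 2.08, Lsp1 by 1.83, Mrpl23 by 1.01, Nadsyn1 by 0.61 and Cd81 by 0.37, while Th (-2.24), Tnfrsf22 (-0.98), Tnfrsf23 (-0.96), Tspan32 (-0.59), Ascl2 (-0.39), Tssc4 (-0.17) and Cttn (-0.13) fell. Nap1l4 (-0.05) and Sez6l2 (0.22) did not pass the test. H19 overlaps Mir675 (5.51) and Igf2 overlaps Igf2os (2.84-fold), so their counts cannot be fully separated. H19 was also higher in the 6 clones of other deletions (30.4 to 111 CPM) than in the parental line (3.27). R74862 (0.45), Gm23297 (1.06), Gm7290 (2.08), Mir7064 (2.21) and Gm33148 (2.00) rose from low levels. Of 34 tested genes within 1 Mb, 19 rose and 7 fell, also when adjusted over the list alone, and genes called higher were 55.9% of the window and 27.6% of all tested genes. Against the other clones 15 were higher and 3 lower, and 0.239% of windows of 34 consecutive tested genes held at least 19 genes called higher over the parental line.

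**Figure D2:**
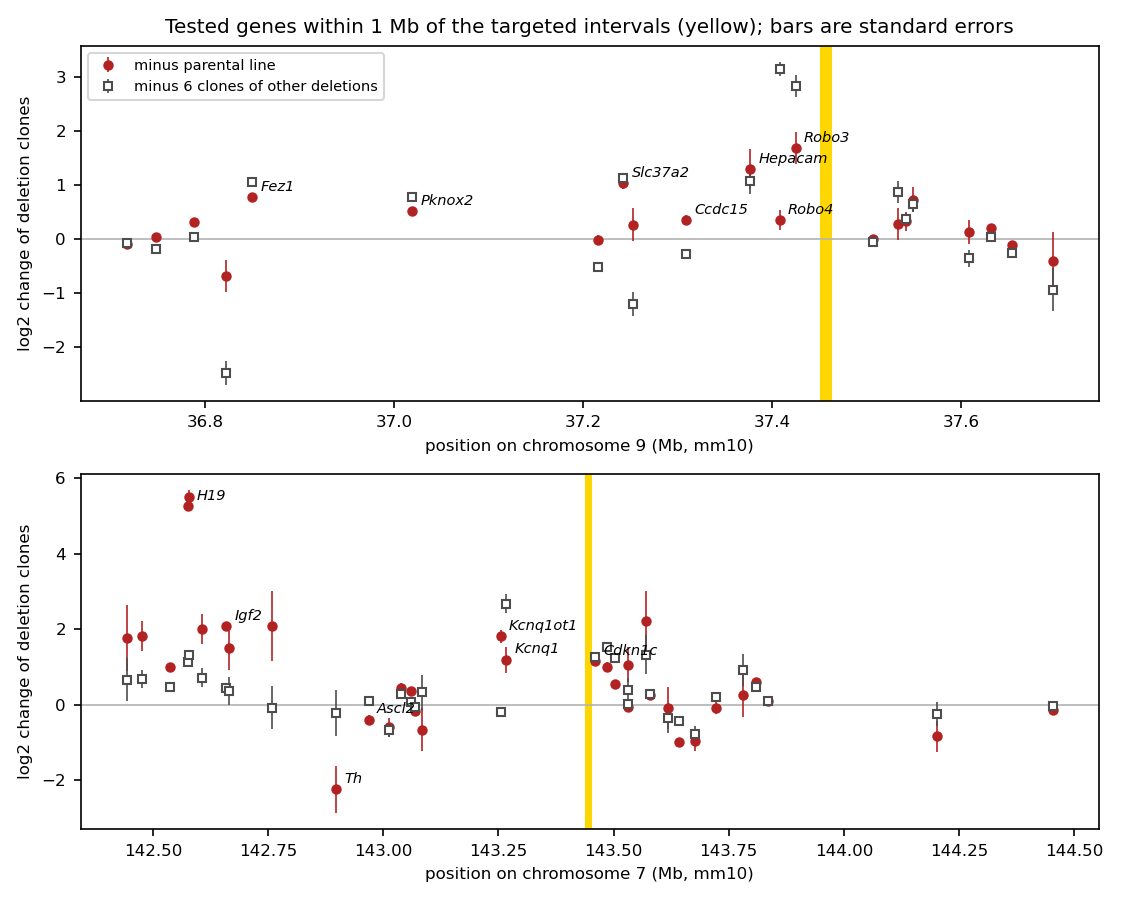
Log2 change (y axis) of each tested gene within 1 Mb of the targeted interval, at the middle of the gene on chromosome 9 (top) and 7 (bottom; x axis in Mb). Red points are the mean of both deletion clones minus the parental line, open squares the same clones minus the 6 clones of other deletions, bars are standard errors and yellow marks the interval. Robo3 (1.69 and 2.84) and Cdkn1c (1.16 and 1.26) were higher in both comparisons.

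The largest fall in the chr7 clones was that of Notum, which encodes a secreted Wnt inhibitor, from 15.6 CPM ± 1.25 (SD, n = 3) to 1.16 ± 0.111 (SD, n = 3) and 1.6 ± 0.392 (SD, n = 3), a log2 change of -3.52. Enox1 (-3.49), Lef1 (-3.47), Myc (-3.37), Id3 (-2.66), Zfp936 (-2.56), Gbx2 (-2.53), Nefh (-2.52), Ttn (-2.51) and Sall3 (-2.50) followed. Beside H19 and Mir675, the largest rises were in Mir6236 (5.42), the elastin gene Eln (8.02-fold), Krt7 (2.70), S100a13 (2.65), Gstm3 (2.59), Gpx6 (2.56), Ldhb (2.44) and Rpl37rt (2.41). Rpl37rt resembles other ribosomal protein genes and Mir6236 is a short locus, so their counts are uncertain. In total 12653 genes were called (5512 higher, 7141 lower), 10077 in the same direction in both clones (4343 higher, 5734 lower; independent lists would share 1300 and 2132). The excess of falls depended on scaling and filter, with 6075 higher and 6556 lower by size factors of the DESeq2 type (RLE), 5963 and 6044 with the compared libraries only and 5470 and 5539 with a filter of at least 1 CPM in 3 libraries. The clones differed from each other in 193 genes, a number that ranged from 48 without chr7-F4 replicate 2 to 593 without chr7-D4 replicate 3. Against the 4 chr3 and chr2 clones, whose libraries had the same range of depth, 7890 genes were called, a comparison chosen after seeing the data. There S100a13 (-0.80), Id3 (0.0322), Th (0.49), Ascl2 (0.18), Cttn (0.0238), Gm7290 (-0.72) and Kcnq1ot1 (-0.31) had the opposite sign to that over the parental line.

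Of the lists, 2-cell-like genes fell in 20 of 23 cases with 0 rises in the chr7 clones (camera adjusted p = 0.000192; adjusted p = 0.125 with an estimated correlation), with Zscan4a at -2.71, Zscan4d at -2.60, Zscan4c at -2.38 and Gm5662 at -2.56. Formative and primed pluripotency genes fell in 16 of 20 cases with 1 rise (0.000192; adjusted p = 0.143 with an estimated correlation), with Foxd3 at -2.74, Dnmt3a at -0.88 and Dnmt3b at 0.501 of its parental level. Naive pluripotency genes fell in 16 of 23 cases with 4 rises (0.0308; adjusted p = 0.448 with an estimated correlation), with Tdh at -1.96, Dppa2 at -1.53, Nr0b1 at -1.37 and Prdm14 at -1.17. Germline genes rose in 13 of 22 cases with 4 falls (0.00941; adjusted p = 0.201 with an estimated correlation), with Sycp3 at 1.43, Mov10l1 at 1.09, Stag3 at 0.85 and Piwil2 at 0.67. Adjusted over the list alone, 5 naive genes rose and 16 fell and 14 germline genes rose and 4 fell. Against the 6 other clones the germline list was not called and turned down (median -0.0755, adjusted p = 0.91), primitive endoderm genes (adjusted p = 0.00838) and Wnt targets (0.0402) were newly called lower and hypoxia (0.00291) and ER stress genes (0.00494) higher, and against the 4 clones of like depth Dnmt3a (0.0804) and Zscan4c (0.20) turned up. The other 20 lists were not called (adjusted p 0.0843 to 0.897), among them Wnt targets (2 higher and 10 lower of 16, adjusted p = 0.0843) and genes with a PRC2 peak within 2 kb (0.846). Feeder markers were lower in 16 of 25 cases (adjusted p = 0.0843 for the list).

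The chr3 clones changed many of the same genes as the chr7 clones. Mir6236 (5.29), H19 (4.60), S100a13 (2.83), Gpx6 (2.75), Fgg (2.46), S100a1 (2.42), Gstm3 (2.37), Rpl37rt (2.34), Dner (2.33) and Ldhb (2.33) rose most. Notum (-2.77), Col1a1 (-2.50), Myc (-2.49), Enox1 (-2.49), Thbs1 (-2.47), Id3 (-2.39), Nefh (-2.34), Lef1 (-2.30), Zfp936 (-2.28) and Gbx2 (-2.28) fell most, and Myc (0.11) and Enox1 (0.52) had the opposite sign against the 6 other clones. Against the 4 chr7 and chr2 clones of like depth, Myc (1.198), Enox1 (1.41), Id3 (0.44), Lef1 (0.33) and Gbx2 (0.26) were above 0 and H19 (-0.17), S100a13 (-0.52) and Mir6236 (-0.0397) below. In total 12156 genes were called (5069 higher, 7087 lower), 9438 in the same direction in both clones (3972 higher, 5466 lower; independent lists would share 1107 and 2043), and 172 differed between the clones, from 61 without chr3-H7 replicate 3 to 150 with other single libraries left out. Here too the excess of falls was smaller with RLE (5593 higher, 6457 lower), the compared libraries only (5843, 6065) and the 1 CPM filter (5093, 5429). Genes called in both clones of both deletions numbered 3376 higher and 4648 lower, with 863 and 1568 for independent lists and 8 in opposite directions. Across genes the log2 changes of chr7 and chr3 had a correlation of 0.879 and a covariance of 0.942, against 0.532 and 0.0107 in simulated unchanged clones with the same 3 control libraries. Part of the excess over independent lists can come from these shared controls, which were too few to split. Library noise in the controls is already in the simulated covariance of 0.0107, so it accounts for little of the 0.942. The chr7 and chr3 libraries also share a range of depth apart from the parental one. That was not simulated and cannot be told apart from the deletions.

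Of the lists, 2-cell-like genes fell in 22 of 23 cases with 0 rises in the chr3 clones (camera adjusted p = 7.63e-07, also called with an estimated correlation, adjusted p = 0.0176), with Zscan4c at -3.53, Zscan4a at -3.14, Gm5662 at -2.98 and Zscan4d at -2.89. Feeder fibroblast markers fell in 23 of 25 cases with 0 rises (5.45e-06; adjusted p = 0.215 with an estimated correlation), with Col1a2 at -2.70 and Col5a2 at -2.87, and Col1a1 was at 2.94 CPM ± 0.758 (SD, n = 3) and 3.54 ± 0.551 (SD, n = 3). Formative and primed genes fell in 15 of 20 cases with 2 rises (0.00281; adjusted p = 0.193 with an estimated correlation), with Foxd3 at -2.12, Sall2 at -1.53 and Dnmt3a at -0.85. ERK targets fell in 14 of 18 cases with 1 rise (0.0145; adjusted p = 0.193 with an estimated correlation), with Junb at -1.35, Etv4 at -0.94 and Ccnd1 at -0.80. Wnt targets fell in 11 of 16 cases with 2 rises (0.019; adjusted p = 0.193 with an estimated correlation), with Cdx1 at -0.94 and Axin2 at -0.75. Hypoxia and glycolysis genes rose in 15 of 22 cases with 4 falls (0.0182; adjusted p = 0.644 with an estimated correlation), with Ddit4 at 1.23, P4ha1 at 0.96 and Pfkl at 0.59, while Egln3 was at -0.88. Adjusted over the list alone, 0 feeder markers rose and 24 fell and 2 Wnt targets rose and 12 fell. Against the 6 other clones the ERK list was not called and turned up (median 0.104, adjusted p = 0.615), the formative list was not called (0.531), germline (0.000814), Hox (3.24e-07) and PRC2 peak genes (0.0202) were newly called lower, and Etv4 (0.13), Axin2 (0.16) and Egln3 (0.16) were higher. Against the 4 clones of like depth Dnmt3a (0.13), Foxd3 (0.13), Etv4 (0.47), Ccnd1 (0.046), Axin2 (0.53), Egln3 (0.14) and P4ha1 (-0.11) also had the opposite sign. The other 18 lists were not called (adjusted p 0.113 to 0.93).

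In the chr2 clones the X-linked Xlr genes rose as in the chr9 clones. Xlr4c rose by 7.64, Xlr3c by 6.72, Xlr5a by 6.60, Xlr5b by 6.37, Xlr4b by 6.31, Xlr5c by 6.13 and Xlr3a by 5.26, with the uncertainty of near-identical copies. Stk33 (6.44), Mir6236 (5.23) and Efhc2 (5.22) were the other leading rises. Spry4, a feedback inhibitor of ERK signalling, fell from 36.9 CPM ± 3.54 (SD, n = 3) to 3.45 ± 0.554 (SD, n = 3) and 8.69 ± 1.12 (SD, n = 3), a log2 change of -2.75. Enox1 (-4.31), Myc (-4.00), Mapk4 (-3.14), Id3 (-2.99), Ina (-2.60), Gbx2 (-2.54), Etv1 (-2.47), Ddx58 (-2.39) and Grb10 (-2.33) also fell. The X-linked median was 0.68 in chr2-D10 and 0.74 in chr2-G5, beside Y-linked RNA at 14.6% and 21.7% of the parental level. In total 13055 genes were called (6233 higher, 6822 lower), 8061 in the same direction in both clones (3854 higher, 4207 lower; independent lists would share 1693 and 1957). More genes were higher than lower with RLE (6540, 6505), the compared libraries only (6440, 6190), the 1 CPM filter (5771, 5484) and against a 1.5-fold change (2450, 1853). The clones differed in 10132 genes, against 6294 for chr9, 193 for chr7 and 172 for chr3. The log2 changes of chr2 and chr9 had a correlation across genes of 0.556 and a covariance of 0.467 (0.561 and 0.0107 simulated), with 1029 shared rises and 849 shared falls where independent lists would give 321 and 315. For chr7 and chr2 the correlation was 0.586 (0.507 simulated; covariance 0.69, simulated 0.0105), for chr3 and chr2 0.518 (0.51 simulated; 0.588, simulated 0.0104), for chr9 and chr7 -0.0079 (0.558 simulated; -0.0063, simulated 0.0105) and for chr9 and chr3 -0.11 (0.579 simulated; -0.0838, simulated 0.0107).

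Of the lists, ERK targets fell in 13 of 18 cases with 2 rises in the chr2 clones (camera adjusted p = 0.0012; adjusted p = 0.126 with an estimated correlation), with Dusp6 at -2.28, Etv4 at -1.63 and Spred2 at -1.05. Formative and primed genes fell in 15 of 20 cases with 0 rises (0.00164; adjusted p = 0.143 with an estimated correlation), with Lef1 at -1.78, Lin28b at -1.11, Dnmt3a at -1.07 and Dnmt3b at -0.93, while Lef1 was higher than in the other clones (0.42). Germline genes rose in 15 of 22 cases with 3 falls (0.00164; adjusted p = 0.126 with an estimated correlation), with Dazl at 2.09, Hormad1 at 1.70, Sohlh2 at 1.45 and Stk31 at 1.41. Hox genes rose in 16 of 28 cases with 0 falls (0.0184; adjusted p = 0.126 with an estimated correlation), with Hoxd9 at 2.81, Hoxd8 at 2.00, Hoxd4 at 1.90 and Hoxc13 at 0.70. Genes of the p53 response rose in 15 of 20 cases with 4 falls (0.0252; adjusted p = 0.441 with an estimated correlation), with Eda2r, an X-linked gene, at 1.76, Perp at 0.82, Sesn2 at -0.60 and Gtse1 at -0.52. Adjusted over the list alone, 15 p53 genes rose and 5 fell. Against the 6 other clones the formative (adjusted p = 0.395), germline (0.443) and p53 (0.314) lists were not called, and against the 4 clones of like depth Lef1 was higher (1.10) and Mir6236 was at -0.12. The other 19 lists were not called (adjusted p 0.0504 to 0.875). No list was tested again without its X-linked genes, whose median was higher in both chr2 clones. Changes of autosomal genes over the parental line cannot be told apart from this difference in sex-linked RNA either.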

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

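Genes named above were singled out where the clones of 1 deletion differed by edgeR's test and their log2 changes from the parental line had opposite signs. In the chr9 clones Esrrb, a naive pluripotency factor, was at 0.00342 in chr9-F1 and -0.65 in chr9-G9, a difference of -0.66 (adjusted p = 5.15e-12). Robo4 was at 1.02 and -0.33, a difference of -1.35 (adjusted p = 1.96e-05), with 5.32 CPM in the parental line, 10.8 in chr9-F1 and 4.21 in chr9-G9. Msantd2, 25.8 kb from the interval, was at 0.17 and -0.16, a difference of -0.34 (adjusted p = 0.000472). By the same test Esrrb in chr9-F1 (adjusted p = 0.972), Robo4 in chr9-G9 (0.194) and Msantd2 in chr9-F1 (0.0783) did not differ from the parental line.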

How the results depend on the processing

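Of 278 alternatives for the counts, shares and tests, 214 kept their direction and side of the threshold or stayed within 1.5 times, among them other size factors, thinned counts and the removal of X and Y genes, though the balance of rises and falls moved with scaling and filter. The cause of a change was not tested unless stated. Controls of the same depth, clone chr9-F1 alone, list tests against other clones, thinning, anchors by 50% inside and means of lines were alternatives chosen after seeing the data. Replicate numbers did not pair the libraries (mean correlation of deviations -0.0043 for equal numbers, -0.521 to 0.406, and 0.0019 for others). With the replicate block 7387, 12573, 12079 and 12973 genes were called for chr9, chr7, chr3 and chr2.

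Against a 1.5-fold change 895, 4004, 3287 and 4303 genes were called for chr9, chr7, chr3 and chr2. For chr9, 14370 differed from the other clones, 4851 were called in chr9-F1 alone, and at 1 percent 2034 were shared by both clones. For chr7, 7890 differed from the 4 clones of like depth. Clone against clone gave 580 (chr7) and 350 (chr3) with no filter, 464 and 390 with DESeq2, and 457 for chr3 with the compared libraries only. With single libraries left out it ranged from 48 to 593 (chr7), 61 to 150 (chr3) and 3899 to 6120 (chr9), and the genes shared by both chr9 clones from 2036 to 3117; a lone library of a clone was assumed to vary like the others. Near the intervals 18 chr9 genes were called against the other clones, and 9 and 47 chr7 genes within 200 kb and 2 Mb, since fewer or more genes were tested. With an estimated correlation 7, 0, 1 and 0 lists were called (chr9, chr7, chr3, chr2). With fry, which does not compare a list with other genes, 20, 19 and 19 were called for chr7, chr3 and chr2, and against other clones 8 for chr7 and 2 for chr2.

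With at least 50% of a PRC2 peak covered, overlap was 9.58% (H3K27me3), 1.58% (CTCF), 6.1% (RNA polymerase II ChIP) and 44.7% (ChIA-PET). In the higher-scoring 50% of peaks it was 27.7%, 8.1%, 11.8% and 66.5%. Both anchors lay in a peak for 19.8% of interactions of at least 6 PETs and 6.98% with anchors extended by 1 kb. The expression difference was -0.0024 for ends in any anchor. With the mean of each line the Ezh2 differences at the intervals were -8.57 (chr9) and -5.68 (chr7) with too few lines to pass the test. At the chr7 interval the difference was -3.33 unscaled and -6.54 to -4.76 with single libraries left out. Near the intervals it was -0.25 (chr9) and 6.08 (chr7) unscaled, and -1.22 to 3.19 and -0.294 to 4.12 with single libraries left out, where it also took -0.253, -0.265, -0.563 and -0.868 for chr9.

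Over 3443 settings of the 212 gene changes named, 3316 kept their call, 73 lost it, 4 gained it and 50 changed sign. Msantd2 in chr9 was at -0.0024 with no filter and -0.0023, -0.013 and -0.018 without parental replicate 1, parental replicate 3 and chr9-F1 replicate 2, and at 0.0325 without parental replicate 2. Nap1l4 in chr7 was at 0.026 with the strict filter and 0.0092 with the compared libraries only. Against the 6 other clones chr9 values were -0.29 (Ccdc15), -0.0509 (Msantd2), -0.36 (Spa17), 0.20 (Zmat4), 0.0939 (Cdc42ep2), 0.38 (Bmp4) and -0.74 (Eda2r). For chr7 they were 0.0924 (Ascl2), -0.0737 (Gm7290), -0.20 (Kcnq1ot1) and 0.0309 (Nap1l4), for chr3 0.11 (Myc), 0.52 (Enox1), 0.13 (Etv4), 0.16 (Axin2) and 0.16 (Egln3), and for chr2 0.42 (Lef1). Against the 4 clones of like depth chr7 values were 0.49 (Th), 0.18 (Ascl2), 0.0238 (Cttn), -0.72 (Gm7290), -0.31 (Kcnq1ot1), 0.0014 (Nap1l4), -0.80 (S100a13), 0.0322 (Id3), 0.0804 (Dnmt3a) and 0.20 (Zscan4c). For chr3 they were -0.0397 (Mir6236), -0.17 (H19), -0.52 (S100a13), 1.198 (Myc), 1.41 (Enox1), 0.44 (Id3), 0.33 (Lef1), 0.26 (Gbx2), 0.13 (Dnmt3a), 0.13 (Foxd3), 0.47 (Etv4), 0.046 (Ccnd1), 0.53 (Axin2), 0.14 (Egln3) and -0.11 (P4ha1), and for chr2 -0.12 (Mir6236) and 1.10 (Lef1).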

Other observations

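Imprinted genes varied between clones beyond the deletions, in genes chosen after their values were seen. H19 had 3.27 CPM ± 0.344 (SD, n = 3) in the parental line and 30.4 to 181 CPM in the 8 clones, and Igf2 had 4.91 ± 0.428 (SD, n = 3) and 9.14 to 24.8. Grb10 had 251 CPM ± 3.56 (SD, n = 3) in the parental line, 26.6 ± 2.59 (SD, n = 3) in chr7-D4 and 188 ± 5.61 (SD, n = 3) in chr7-F4, clones that otherwise differed in 193 genes. Klhl13, an X-linked gene, had 161 CPM in the parental line, 778 in chr2-D10 and 1100 in chr2-G5, and the X-linked ERK phosphatase gene Dusp9 had 127, 435 and 356. In chr9-F1 and chr9-G9 Klhl13 had 199 and 314 CPM and Dusp9 200 and 286.

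The tests on clone pairs, on clones of like depth, on the sex chromosomes and on a pseudogene batch were chosen only after values they measure had been seen, and those on windows and on thinning after the data but before their own values. The first pattern is the rise of genes near the deleted intervals. For chromosome 7, 1 of the 28 pairs of clones, the chr7 pair, had as high a median difference from the 6 other clones over the 34 genes within 1 Mb (0.311, next highest 0.203), 0.239% of windows held as many rises, and 0.0739% had as high a median over clones of the same range of depth (0.234). The clone-pair share of 3.57% is the smallest possible, and the test repeats an excess already seen, so it cannot exclude variation between clones. The window shares argue against neighbouring genes that move together anywhere and against depth. However, windows were not matched for imprinted genes, which varied between clones. A link between the deletion and the rise around Cdkn1c remains as a hypothesis. For chromosome 9, 5 of the 28 pairs had a median as high as the chr9 pair (0.0297, highest 0.308) and 5.98% of windows held as many rises, so either explanation may account for the neighbourhood as a whole. Robo3 itself was not tested in this way.

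The second pattern is a lower sum of Y-linked RNA with higher X-linked RNA in the chr9 and chr2 clones, where Xist, the RNA of the inactive X, had 0.919 to 2.61 CPM against 0.176. Zfy1 and Uba1y had 0 counts (up to 0.022 CPM by counting error alone; 0.487 CPM of Zfy1 in the parental line) and Ddx3y 0.0453 to 0.385 CPM against 4.54, but chr9-G9 kept Kdm5d at 0.16 against 0.207 and Eif2s3y at 0.407 against 1.13, and Gm20775 was higher in all 4 clones (0.865 to 1.9 against 0.725). Loss of the Y alone would leave X-linked genes at the autosomal level, but the lowest difference of medians was 0.296 ± 0.0171 (SE). Feeder RNA would dilute the Y-linked RNA, but to lower it to 21.7% of the parental sum, the highest of these clones, feeders would have to supply most of the RNA. A second X chromosome or another origin of these clones was not tested and stays open.

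The third pattern is a rise of 136 annotated pseudogenes in the chr7, chr3 and chr2 clones, with medians of 0.991 to 1.18 against -0.0791 and 0.149 in the chr9 clones. After all libraries were thinned to the smallest total the lowest median was 1.12. Thinning leaves the expected CPM ratios of genes with many counts unchanged, so it could not decide whether fewer counts were the cause. The gap of 0.842 between the lowest of these 6 clones and the higher chr9 clone may come from a library or sequencing batch. No line had libraries of both ranges of depth, so batch and deletion cannot be told apart, and no biological explanation was tested.

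Splits were first drawn 25 times and, after those were seen, extended to 60 with the same seed. Of 60 drawn splits of the libraries of 1 deletion and the parental line, fitted alone, 1 gave as many called genes as the real split for each deletion: 8413 for chr9 (highest other 6787), 12007 for chr7 (11976), 11908 for chr3 (11548) and 12630 for chr2 (8043). For genes shared by both clones 1 split did so for chr9 (3787, highest other 3202), chr3 (9560, 9466) and chr2 (7979, 5285), and 2 for chr7 (9769, 9804). A chance assignment of these libraries was thus excluded at 5 percent, but chance differences between lines were not, since few draws keep the parental line whole. Among splits that separated the parental libraries the highest count of called genes was 511 for chr9 and 0 for the other deletions, and those that kept them together came close to the real count for chr7 and chr3. For clone against clone only 10 splits exist, too few for a share under 5 percent. The real split gave 47, 299 and 9534 genes for chr7, chr3 and chr2 and was the 1 with the most, and the highest other was 0.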
